A study of Rattus norvegicus with 4 samples.

How the data were processed

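The samples were kidney allografts of Lewis rats treated with an ApoE-mimetic peptide or a control peptide. Per the labels, total RNA was labelled with Cy3 and Cy5 for two-colour Agilent arrays in a balanced dye swap with 4 biological replicates on 4 arrays. The 4 arrays form 1 group for the tests, since each holds a sample of both peptides. The labels do not say whether any samples beyond the replicates were pooled. The deposited values are taken as log2 ratios of the channels of each array. The scanner, background correction and normalization are not given in the sources used here. The log base is unstated and was read from the values, since the largest absolute value, 11.33, exceeds 11.09, the natural log of the range of a 16-bit scanner. As the scanner is not given, that range is an assumption and the log base is not settled by it. The direction of the ratios is also unstated.

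The deposited columns were not centred. Their medians were -0.17, -0.04, -0.10 and -0.58 for replicates 1 to 4, and their SDs were 0.89, 0.88, 0.87 and 1.26. Values were missing for 48, 58, 26 and 39 features. On each array between 59.1% and 67.6% of the features held a value shared exactly with another feature, which is taken here as a sign of a dim feature. Of these features, 104 to 230 per array shared a single value next to 0, among them 12 features of B2m and 10 of Rplp1, and are taken instead as saturated in both channels. A feature counted as neither dim nor saturated where at most 2 features held its value on each array and it was not at the shared value next to 0, which left 13363 features and 6731 named genes. The table has no flags for control features, so all 45220 features were tested. The array annotation gave 1 gene symbol for 25353 features, several for 48 and none for 19819. By gene number, 25306 features were found in a RefSeq table of the GRCr8 assembly, and 1 symbol was updated. Of the resulting genes, 9120 have 1 feature and 5751 have more, and a gene's value on an array is the mean over its features.

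Ratios were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with a treatment coefficient, given by the labelled dye orientation, and a dye coefficient, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Values are uncentred, so a named gene's ratio includes the array offsets, which leave a median of 0.04 over all genes in the treatment coefficient and -0.24 in the dye coefficient. The dye coefficient is the treatment effect if the authors had already turned the columns. For the 39 gene lists, written before the data were examined, camera used a preset correlation of 0.01 with the same model, and camera with an estimated correlation, camera on ranks and fry were run as alternatives. With an estimated correlation, camera rests on the few residual degrees of freedom of 4 arrays and could hardly call any list here. A call lost under it is therefore weak evidence in either direction. Medians of lists were taken after centring each array on its median gene, and compared with 10000 random lists with the same number of genes with a feature that is neither dim nor saturated. All tests were two-sided. With 4 arrays an exact sign-flip test cannot give a p under 0.125. No scan date or slide was used. The p-values and SEs of single genes and features rest on the spread left after the dye term, between arrays of 1 labelled orientation, as moderated by eBayes. They do not measure the spread over the 4 pairs. Icos, with 0.66, 2.55, -0.77 and 3.43 on replicates 1 to 4, has an SE of 0.37. The p-values of camera with the preset correlation compare a list's genes with the other genes and take members as nearly independent. They do not measure the spread of a list between the pairs.

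The genes named in the text follow a rule set before the data were examined. It takes up to 8 genes per direction with an adjusted p under 0.05 and 1 sign on all 4 arrays, ordered by size and filled, where fewer pass, with the genes of 1 sign on all 4 arrays with the smallest unadjusted p, passing over placeholder symbols. It adds up to 4 members with the smallest unadjusted p for each list described, and Apoe, Lrp1, Lrp8 and Vldlr; a further item of the rule is not reported here. Genes outside the rule are named as such.

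The tests were run on simulated data first. With 100 of 14847 genes changed by 2 log2 units and 100 by 4, 3% and 80% were recovered, and 6 unchanged genes were called. With dim features left out, 84% and 96% were recovered among 6731 genes, with 5 unchanged genes called. A list shifted by 1 log2 unit was called among 39 lists with 0 other lists called, and 0 lists were called where nothing was changed. The simulated noise was independent between genes. It therefore cannot show how often lists whose members move together are called without a change. The alternatives were leaving out the dye term, centring, scaling the arrays to 1 median absolute deviation, array weights, robust eBayes, the other reading of the columns, leaving out each replicate, the median over features, genes with 1 feature, a filter on the lower quartile of absolute ratio and other thresholds. Leaving out dim features, removing the spatial trend in windows of 21 by 21 features on the 85 by 532 grid, and testing only features with 1 gene symbol were added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.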

Results

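The series profiled gene expression in rat kidney allografts. Lewis rats carrying an allogeneic kidney received a peptide that mimics apolipoprotein E (ApoE), at 6 mg/kg, or a control peptide, injected into a vein every day from the day of transplantation. The grafts were taken on day 4. The series title names a protective role of ApoE in acute rejection, and the comparison asks which graft transcripts differ between the peptides. Each of 4 two-colour Agilent arrays held 1 ApoE-mimetic sample and 1 control sample, so every measurement is a ratio between paired samples. Per the labels, ApoE-mimetic RNA carried Cy5 on replicates 1 and 3 and Cy3 on replicates 2 and 4, and the replicates are biological. The table gives a log2 ratio for 45220 array features, of which 25353 bear 1 gene symbol and represent 14871 genes. No intensities were used here, and the number of arrays limits the precision. Replicate 4 differed from the others. Its ratios had an SD of 1.26 against 0.87 to 0.89, and its median ratio moved from -0.80 over the first 10 columns of the array grid to 0.40 over the last 10.

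**Figure D1:**
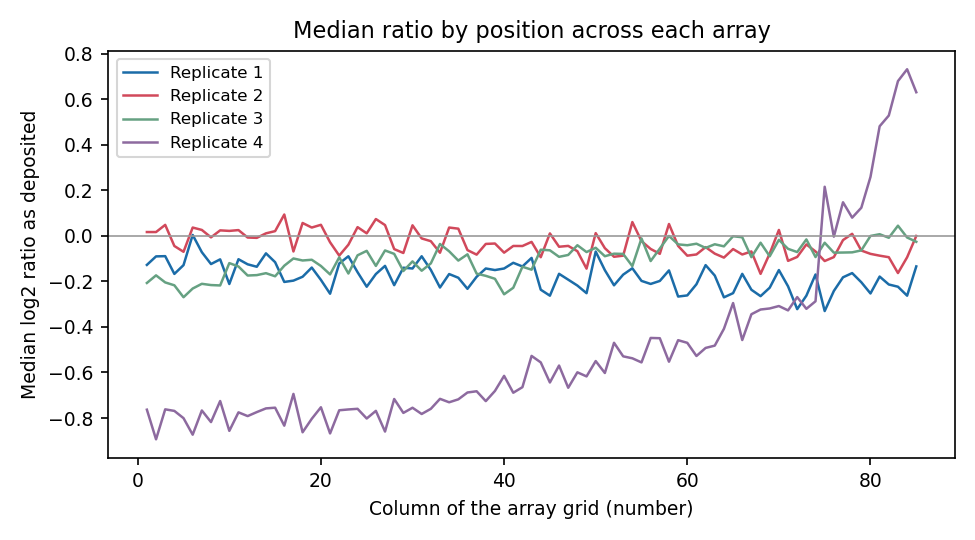
Median deposited log2 ratio (vertical axis) of the features in each of the 85 columns of the array grid (horizontal axis), with 1 line per array. The line of replicate 4 climbs across the array, and grid column explained 9.06% of its variance against 0.41% to 0.63% on the other arrays.

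Neither the labels nor the values settled which peptide each deposited ratio has in its numerator. Replicates 1 and 3 share a dye orientation, yet their ratios ran against each other, with a Pearson correlation of -0.657 across the 13363 features that were neither dim nor saturated and -0.238 across all features. Replicates 2 and 4, of the other orientation, had a correlation of -0.04 across those 13363 features. Genes are not independent replicates in such correlations. Following the rule fixed before the data were examined, the columns were read as Cy5 over Cy3, and replicates 2 and 4 were turned. That rule rested on pairs of features of 1 gene, whose correlation was 0.083 for the component that alternates with dye orientation and 0.065 for the component common to all columns, and the difference of 0.019 had a 95% bootstrap interval from -0.029 to 0.063. The component of replicates 1 and 4 against 2 and 3 had a higher value, 0.169, and over features neither dim nor saturated it had 0.764 against 0.534 and 0.502. That component would be the comparison of the peptides if the labels of replicates 3 and 4 were exchanged. With its sign turned, it would also be so if those of replicates 1 and 2 were exchanged. Both are left open. All signed values below therefore hold for this reading of the columns. If Cy3 is the numerator instead, every sign turns and every p-value stays, and the counts of genes and lists for columns already turned by the authors are given beside the main ones.

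**Figure D2:**
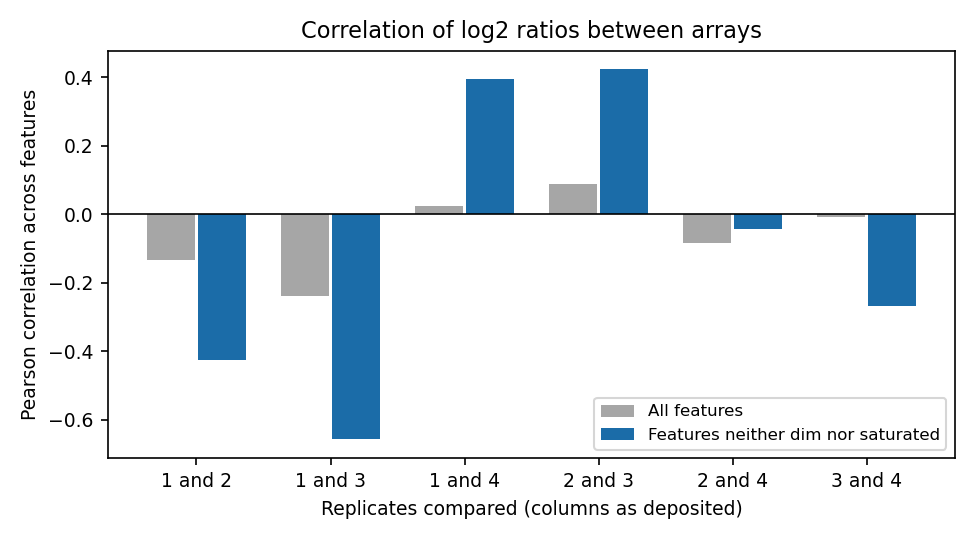
Pearson correlation of deposited log2 ratios across features (vertical axis) for each pair of the 4 arrays (horizontal axis), over all features (grey bars) and over features neither dim nor saturated (blue bars). Replicates 1 and 3, of the same labelled dye orientation, had the lowest value, -0.657, and replicates 2 and 3, of opposite orientation, had 0.423.

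T cell, cytotoxic and proximal tubule transcripts differed between the channels of every array, whichever peptide they favoured. The ratio of a single array holds any dye effect along with a difference between grafts. With columns read as Cy5 over Cy3, T cell markers shifted by -0.76 relative to all genes in the dye coefficient, against 0.50 in the treatment coefficient. The median T cell marker lay between 0.63 and 1.63 log2 units away from the array's median gene, in either direction, with a mean distance of 1.22 over 4 arrays. Cytotoxic and natural killer cell genes lay at a mean distance of 1.04, and regulatory T cell and checkpoint genes at 0.97. Proximal tubule markers, which include the transporters of the reabsorbing epithelium, lay at a mean distance of 1.22. Of 39 gene lists, 8 had a median outside the central 95% of random lists on all 4 arrays and 12 on 0 arrays. Besides those named, these 8 were the monocyte and macrophage, cell cycle, complement and chemokine lists.

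Cytotoxic genes, regulatory T cell and checkpoint genes, chemokines, antigen presentation genes, and smooth muscle and renin cell markers lay on the same side as T cell markers on 4 of 4 arrays. Proximal tubule markers lay on the opposite side from T cell markers on replicates 1, 2 and 3, and on the same side on replicate 4. Monocyte and macrophage markers, cell cycle genes and complement genes lay on the side opposite to proximal tubule markers on 4 of 4 arrays, whereas podocyte, collecting duct, endothelial and fatty acid oxidation genes lay on the proximal tubule side on 4 of 4. Further lists on the side opposite to proximal tubule markers on all arrays were alternatively activated macrophage and skeletal muscle genes. Further lists on the proximal tubule side were oxidative stress, endothelial activation and coagulation, and immediate early and heat shock genes. The smooth muscle, skeletal muscle, endothelial activation and immediate early lists lay outside the central 95% of random lists on 0 of 4 arrays, so their sides carry little weight. A list falls on the same or the opposite side of another on all 4 arrays by chance in 12.5% of cases. Of the other lists, 5 lay on the same side as T cell markers on all arrays and 2 on the opposite side, and for proximal tubule markers these counts were 7 and 5, so such runs were common in this collection of lists.

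No single gene passed the test between the peptides. With limma, 0 of 14871 genes had an adjusted p under 0.05, the lowest adjusted p was 0.9999, and 383 genes had an unadjusted p under 0.05 where 743.55 would be expected by chance. Among features, 0 of 45220 passed, and 1352 had an unadjusted p under 0.05. The ratios of 1216 genes, 8.18%, had 1 sign on all 4 arrays, and 17.8% did with columns taken as already turned. The array offsets are left in these shares and move them, so neither is set against a share by chance. With columns taken as already turned by the authors, 0 genes passed again, with 486 at an unadjusted p under 0.05 and a lowest adjusted p of 0.825. On data simulated with the spread of these arrays, 3% of genes changed by 2 log2 units and 80% of genes changed by 4 were recovered. With dim features left out, 84% of genes changed by 2 log2 units were recovered. There 0 of 6731 genes passed and 42 had an unadjusted p under 0.05, where 336.55 would be expected by chance. The simulation took the labels as right and its noise as independent between genes, which would give about the chance count. Its noise is therefore unlike that of these arrays, and its shares do not apply if the labels of replicates 3 and 4, or of 1 and 2, were exchanged.

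The genes with the smallest p among those of 1 sign on all 4 arrays did not pass either. On the ApoE side these were Hpx, which encodes the heme scavenger hemopexin, at 2.13 log2 units (SE 0.29, n = 4), Aire at 1.81 (SE 0.27), Znhit1 at 1.68, Calhm5 at 1.99, Pard6g at 1.41, the class I histocompatibility gene RT1-CE6 at 2.20 (SE 0.42), Or52n2b at 1.38 and the sodium channel gene Scn10a at 1.31. On the control side they were Pik3ip1, an inhibitor of phosphoinositide 3-kinase, at -2.02 (SE 0.36), Ccdc163 at -1.67, Rec114 at -1.84, Inka1 at -1.42, the lipid phosphatase gene Inppl1 at -1.93 (SE 0.38), Zbtb14 at -2.07, the somatostatin receptor gene Sstr3 at -1.57 and Rasl11b at -1.46. Each of these 16 genes is represented by 1 feature that was dim or saturated on at least 1 array. With columns taken as already turned, Hpx had -0.20, Aire -0.58, RT1-CE6 0.24, Pik3ip1 -0.50 and Inppl1 -0.13.

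Apoe itself and the receptors named here showed no difference that passed the test. Apoe, whose protein the peptide mimics, had a log2 ratio of 0.25 (SE 0.30, n = 4), positive on 2 of 4 arrays, and -0.69 with columns taken as already turned. Lrp1 had -0.31 (SE 0.29), Vldlr 0.33 (SE 0.33) and Lrp8 0.14 (SE 0.38). When 1 replicate was left out, Apoe ranged from 0.02 to 0.48, Lrp1 from -0.50 to -0.11, Vldlr from 0.05 to 0.62 and Lrp8 from -0.24 to 0.52. Every feature of Lrp1, Vldlr, Lrp8 and Lrp4 was dim or saturated on at least 1 array, and only 5 of the 13 receptor genes measured had a feature that was neither, so these values are weak evidence for or against a difference. Of the 13 ApoE receptor genes measured, 0 passed over all genes and 0 when adjusted over the list alone, with Lrp4 at -1.19 (SE 0.58) and Trem2, a lipid-sensing receptor of macrophages, at -1.09 (SE 0.54). Among 22 LXR target and lipoprotein genes, 0 passed by either adjustment, with Lpl at 0.61 (SE 0.32) and Cd36 at -0.31 (SE 0.31; -0.49 with dim features left out). The shift of the ApoE receptor list had an adjusted p of 0.11, and that of the lipoprotein list 0.49. Over the 5 receptor genes left without dim features, the list was called toward the control peptide at an adjusted p of 0.047, and lost at adjusted p = 0.955 with an estimated correlation.

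T cell markers shifted as a group relative to other genes, toward the ApoE-mimetic peptide under this reading. Their median relative to the array's median gene was 0.58 ± 1.31 (SD, n = 4), positive on replicates 1, 2 and 4 (0.63, 1.63 and 1.36) and negative on replicate 3 (-1.29). The limma camera test with a preset correlation gave an adjusted p of 0.000232, and the call was lost at adjusted p = 0.935 with an estimated correlation. An exact sign-flip test over the 4 array medians gave p = 0.375. With columns taken as already turned, the shift was toward the control peptide, with an adjusted p of 2.52e-06, and adjusted p = 0.983 with an estimated correlation. Without replicate 1 the adjusted p under the main reading was 0.614 and the shift relative to all genes 0.07, against 0.50 with all arrays, and without replicate 2 they were 0.42 and 0.34. With the dye term also left out, the shift was 0.47 without replicate 1 (adjusted p of 0.0988) and 0.14 without replicate 2 (adjusted p of 0.742), so its size depends on the model as well as on the replicate. Of 18 members, 0 passed over all genes and 0 when adjusted over the list alone. Icos, a costimulatory receptor, had 1.47 (SE 0.37), Trat1 1.14 (SE 0.38), the adaptor Sh2d1a 0.97 (SE 0.31) and Cd3g, a chain of the T cell receptor complex, 0.83 (SE 0.39). The 1 feature of Trat1 was dim or saturated on at least 1 array.

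Cytotoxic and natural killer cell genes shifted on the same arrays. Their median was 0.41 ± 1.14 (SD, n = 4), positive on 3 of 4 arrays, with an adjusted p of 0.00431, and adjusted p = 0.935 with an estimated correlation. Without replicate 1 the shift relative to all genes turned to -0.04 (adjusted p of 0.954), against 0.45 with all arrays, though with the dye term also left out it kept its direction, at 0.35 (adjusted p of 0.12). Of 15 members, 0 passed over all genes and 0 when adjusted over the list alone. Gzmb, which encodes granzyme B, had 1.08 (SE 0.49), Ifng, encoding interferon gamma, had 0.77 (SE 0.34), and Gzmc had 0.70 (SE 0.39). Regulatory T cell and checkpoint genes had a median of 0.59 ± 0.97 (SD, n = 4), positive on 3 of 4 arrays, with an adjusted p of 0.0348 and adjusted p = 0.935 with an estimated correlation. The shift relative to all genes fell from 0.44 to 0.01 without replicate 1 (adjusted p of 0.92) and to 0.28 without replicate 2 (0.664), and with the dye term also left out these were 0.34 (0.278) and 0.14 (0.836). With all arrays the call was lost without the dye term, at an adjusted p of 0.0726, and with scaled arrays, at 0.0649. Among them Lag3 had 0.89 (SE 0.52), Tnfrsf18 0.78 (SE 0.35) and the interleukin 2 receptor gene Il2ra 0.86 (SE 0.59; 0.72 with dim features left out), and 0 of 11 passed by either adjustment, over all genes or adjusted over the list alone. Each of these 3 lymphocyte lists was on the control side on replicate 3.

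**Figure D3:**
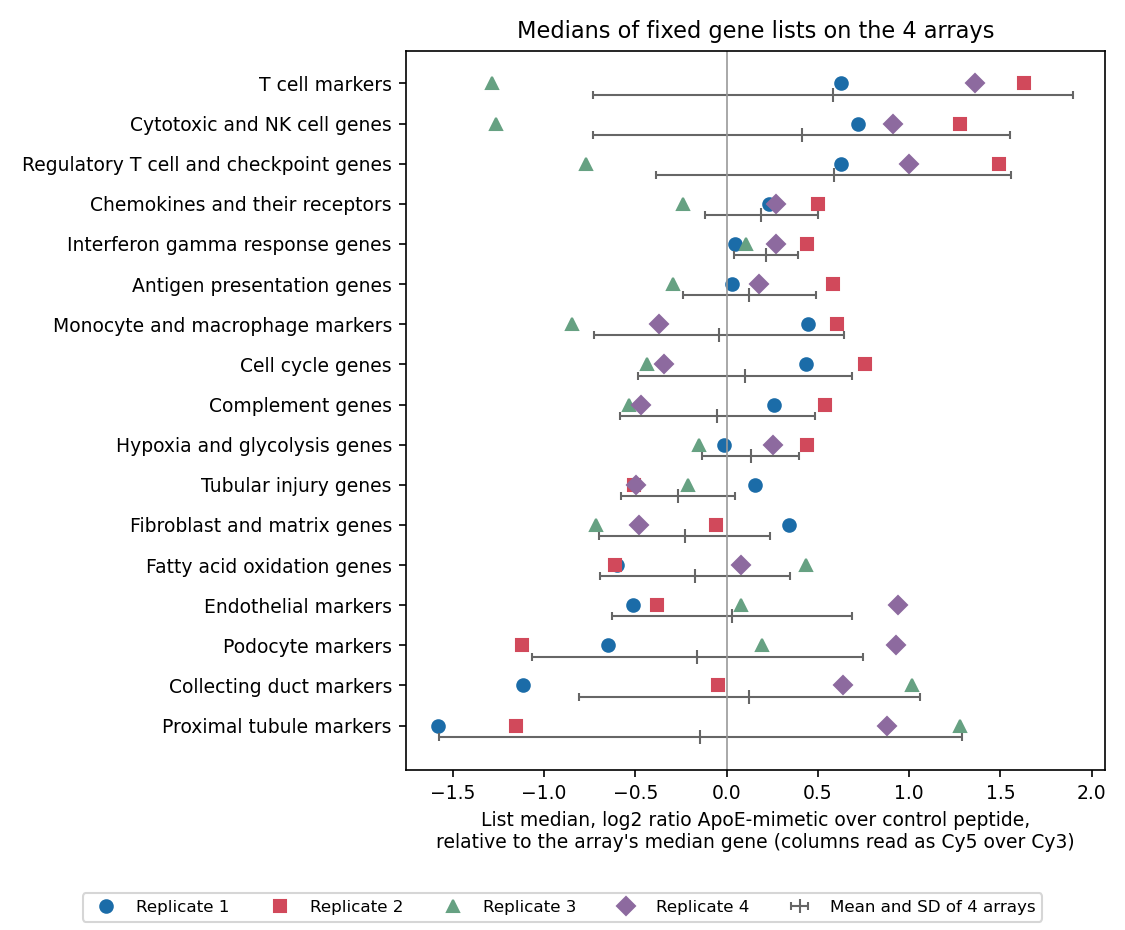
Median log2 ratio of ApoE-mimetic over control peptide for 17 fixed gene lists (vertical axis), relative to the array's median gene (horizontal axis, columns read as Cy5 over Cy3), with 1 symbol per replicate and a grey bar for the mean and SD of 4 arrays. T cell markers lay at 0.63, 1.63 and 1.36 on replicates 1, 2 and 4 and at -1.29 on replicate 3, and proximal tubule markers at -1.58 and -1.15 on replicates 1 and 2 and at 1.28 and 0.88 on replicates 3 and 4.

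Interferon gamma response genes shifted by less but with 1 sign on 4 of 4 arrays. Their median was 0.22 ± 0.18 (SD, n = 4), the adjusted p was 0.0125, and adjusted p = 0.935 with an estimated correlation. The shift relative to all genes was 0.24 with all arrays. The call was lost without replicate 2 (shift 0.18, adjusted p of 0.319) and without replicate 3 (0.23, 0.0947). With the dye term also left out, it was lost without replicate 2 (0.12, 0.572) and replicate 4 (0.20, 0.101). It was kept there without replicate 3 (0.31, 0.0278). An exact two-sided sign-flip test over the 4 array medians gave p = 0.125, the smallest that 4 arrays allow. Chance gives 1 sign on all 4 arrays in 12.5% of cases. The dendritic cell, inflammatory cytokine and NF-kB, erythroid and adipocyte lists had it too, the last 2 toward the control peptide. The interferon gamma list lay outside the central 95% of random lists on 1 of 4 arrays. Among the 23 interferon gamma response genes, 0 passed over all genes and 0 adjusted over the list alone. Ido1, which encodes a tryptophan-degrading enzyme, had 1.31 (SE 0.36), Gbp4 0.60 (SE 0.28), Ubd 0.73 (SE 0.35) and the chemokine gene Cxcl11 0.53 (SE 0.28). Ido1 was positive on 2 of 4 arrays and had -1.74 with columns taken as already turned. The 1 feature of Ubd held the shared value next to 0, taken here as saturation, on replicates 1 and 3. Chemokines and their receptors had a median of 0.19 ± 0.31 (SD, n = 4), positive on 3 of 4 arrays, with an adjusted p of 0.0236, which became 0.0618 without the dye term, and adjusted p = 0.935 with an estimated correlation. The shift relative to all genes was 0.18 with all arrays, 0.11 without replicate 1 (adjusted p of 0.337) and 0.09 without replicate 2 (0.488), and with the dye term also left out it was 0.19 (0.114) and 0.06 (0.742). Ccl5 had 0.83 (SE 0.34), Ccl4 0.64 (SE 0.32) and Cxcl13 0.71 (SE 0.36; 1.28 with dim features left out), and 0 of 32 passed by either adjustment, over all genes or adjusted over the list alone. Ccl5 was positive on 2 of 4 arrays and had -1.33 with columns taken as already turned. Type I interferon response genes had an adjusted p of 0.0513 and antigen presentation genes 0.0699, so neither list passed over all features. With dim features left out both were called, at 6.38e-06 and 0.000155, and lost at adjusted p = 0.831 and adjusted p = 0.68 with an estimated correlation.

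Tubular injury genes and fatty acid oxidation genes shifted toward the control peptide under this reading. The tubular injury list had a median of -0.27 ± 0.31 (SD, n = 4), negative on 3 of 4 arrays, with an adjusted p of 0.0138 and adjusted p = 0.935 with an estimated correlation. The shift relative to all genes was -0.25 with all arrays. The call was lost without replicate 2 (shift -0.32, adjusted p of 0.154), replicate 3 (-0.21, 0.132) and replicate 4 (-0.19, 0.0858). With the dye term also left out, it was lost without replicate 2 (-0.23, 0.257) and replicate 4 (-0.14, 0.199). It was kept there without replicate 3 (-0.29, 0.0369). Of its 27 members 23 lay below the median gene, 0 passed over all genes and 0 adjusted over the list alone, with Cd24 at -0.76 (SE 0.28; -0.38 with dim features left out) and Krt20 at -0.68 (SE 0.29). The 1 feature of Krt20 was dim or saturated on at least 1 array. Havcr1, which encodes kidney injury molecule 1, had -0.60 (SE 0.30), with 0.41 and 1.35 on replicates 1 and 3, -2.15 on replicate 2 and a negative ratio on replicate 4, so its value as deposited was positive on 4 of 4 arrays. Fatty acid oxidation genes had a median of -0.17 ± 0.52 (SD, n = 4), negative on 2 of 4 arrays, with an adjusted p of 0.0138 and adjusted p = 0.942 with an estimated correlation. Without replicate 1 the shift relative to all genes turned to 0.06 (adjusted p of 0.801), though with the dye term also left out it kept its direction, at -0.07 (adjusted p of 0.479), and with columns taken as already turned the call was lost, at an adjusted p of 0.426. Of these 31 genes 30 lay below the median gene and 0 passed by either adjustment, over all genes or adjusted over the list alone, with Eci1 at -0.80 (SE 0.30; -0.05 with dim features left out), Acads at -0.72 (SE 0.41; -0.29 with dim features left out) and Pdk4, a brake on glucose oxidation, at -0.68 (SE 0.35). Each feature of Pdk4 was dim or saturated on at least 1 array. Proximal tubule markers, which lay on the same side as fatty acid oxidation genes on 4 of 4 arrays and as tubular injury genes on 1 of 4, had a median of -0.14 ± 1.43 (SD, n = 4) and an adjusted p of 0.419.

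Of the 10 lists called with the preset correlation, 6 lay on the ApoE side and 4 on the control side. The remaining calls were fibroblast and matrix genes at a median of -0.23 ± 0.47 (SD, n = 4; adjusted p of 0.0408, and adjusted p = 0.942 with an estimated correlation), erythroid genes at -0.47 ± 0.49 (SD, n = 4; adjusted p of 0.0348, and adjusted p = 0.935 with an estimated correlation), and hypoxia and glycolysis genes at 0.13 ± 0.27 (SD, n = 4; adjusted p of 0.0469, and adjusted p = 0.935 with an estimated correlation). Col3a1, a fibrillar collagen gene, had -0.64 (SE 0.44; -0.43 with dim features left out), Hbb, a beta globin gene, had -0.96 (SE 0.35), and Pgk1, a glycolytic enzyme gene, had 0.37 (SE 0.27). Each feature of Hbb was dim or saturated on at least 1 array. Without replicate 3 the shift of the fibroblast list relative to all genes turned to 0.10 (adjusted p of 0.624), against -0.18 with all arrays. It turned to 0.02 (0.957) with the dye term also left out. The fibroblast call was also lost without replicate 2 (-0.36, 0.154) and replicate 4 (-0.01, 0.527) and kept without replicate 1 (-0.47, 0.000128). With all arrays it was lost without the dye term, at an adjusted p of 0.0542. Only 1 of the 9 erythroid genes had a feature that was neither dim nor saturated. With an estimated correlation 0 of 39 lists were called, and fry called 0. The test with an estimated correlation gave 0 lists an unadjusted p under 0.05. Chemokines, with an estimated correlation of 0.0092, near the preset of 0.01, went from an unadjusted camera p of 0.00362 to 0.099. With 4 arrays that test could hardly call any list. Losing a call there therefore shows neither that a list's members move together nor that a list did not shift. Without replicate 2, 0 lists were called with the preset correlation. The erythroid call was also lost without replicate 1 (shift -0.35, adjusted p of 0.0835) and replicate 3 (-0.37, 0.0947), against a shift of -0.36 with all arrays. With the dye term also left out it was kept in both (0.0393 and 0.034). The hypoxia and glycolysis call was lost without replicate 1 (shift 0.08, 0.529) and replicate 3 (0.22, 0.0947), against 0.15 with all arrays. With the dye term also left out it was lost without replicate 1 (0.0841) and replicate 4 (0.333) and kept without replicate 3 (0.0226). With dim features left out 14 of 32 lists tested were called with the preset correlation and 0 with an estimated one. These 14 were the lists called over all features except erythroid genes, which were not tested there, with the type I interferon, antigen presentation, inflammatory cytokine and NF-kB, cell cycle and ApoE receptor lists gained. With columns taken as already turned, 10 lists were called, 7 of them also called under the main reading, and all 7 had the opposite direction. Under that reading the adjusted p was 0.000266 for cytotoxic genes, 0.0415 for regulatory T cell genes, 0.0105 for interferon gamma response genes, 0.0491 for chemokines and for tubular injury genes, and 0.00145 for hypoxia and glycolysis genes, each with adjusted p = 0.983 with an estimated correlation. The hypoxia and glycolysis call under the main reading was also lost without the dye term, with centred or scaled arrays and with the spatial trend removed, at adjusted p from 0.0721 to 0.112, while the shift stayed between 0.13 and 0.15.

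Among the other cell type lists, none was called over all features. Monocyte and macrophage markers had a median of -0.04 ± 0.69 (SD, n = 4; adjusted p of 0.942), with the mannose receptor gene Mrc1 at -0.81 (SE 0.64) and Cd86 at 0.59 (SE 0.48). Each feature of Cd86 was dim or saturated on at least 1 array. Podocyte markers had -0.16 ± 0.91 (adjusted p of 0.806), endothelial markers 0.03 ± 0.66 (0.797), collecting duct markers 0.12 ± 0.94 (0.949) and cell cycle genes 0.10 ± 0.59 (0.196), each as SD over 4 arrays. With dim features left out, cell cycle genes were called at an adjusted p of 0.000651, and lost at adjusted p = 0.955 with an estimated correlation. For the monocyte and macrophage list and the endothelial list, the direction of the test was opposite to the sign of the median. Neutrophil markers had an adjusted p of 0.902, B and plasma cell markers 0.826, dendritic cell markers 0.0513, and mast cell and eosinophil markers 0.826. The markers of tissues that a graft sample could carry along, urothelium, adrenal cortex, adipose tissue and skeletal muscle, had adjusted p values of 0.733, 0.747, 0.11 and 0.125. The loop of Henle and distal nephron list had an adjusted p of 0.191, alternatively activated macrophage genes 0.546, smooth muscle and renin cell markers 0.875, inflammatory cytokine and NF-kB genes 0.232 (0.0125 with dim features left out, and adjusted p = 0.68 with an estimated correlation there), endothelial activation and coagulation genes 0.65, and complement genes 0.826. Among the metabolic and stress lists that did not pass, cholesterol synthesis had 0.631, oxidative phosphorylation 0.902, apoptosis and p53 genes 0.49, immediate early and heat shock genes 0.797, and oxidative stress response genes 0.49.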

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

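All tests of explanations in this part were chosen after the results were seen. Across 39 list medians, 174 named genes and 4 array properties, 217 in all, 9 had 1 array far from the other 3 by Dixon's ratio. Chance flags about 1 in 20, so 9 is not more than chance gives. Of these 9, 5 concerned replicate 4. The inflammatory cytokine and NF-kB list had a median of 0.35 on replicate 4 and 0.02 to 0.06 on the others. Lrp1 had -0.95 on replicate 4 against -0.17 to -0.01, and Zbtb46, a dendritic cell transcription factor gene, had 2.33 on replicate 4 against 0.30 to 0.40. Mcpt1, a mast cell protease gene, had 1.28 on replicate 2 against 0.40 to 0.54, and Il5ra, the interleukin 5 receptor gene, had -0.33 on replicate 2 against 0.84 to 1.02. Pvalb, a gene of the distal nephron, had 1.30 on replicate 3 against 0.09 to 0.28, and C3ar1, a complement receptor gene, had -3.14 on replicate 3 against -0.21 to 0.18. Every feature of Lrp1, Zbtb46, Il5ra, Pvalb and C3ar1 was dim or saturated on at least 1 array. Such features had an SD of 1.45 on replicate 4 against 0.94 to 0.95 on the others.

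Replicate 4 had an SD of 1.26 over all features against 0.87 to 0.89 on the other arrays, and the column of the array grid explained 9.06% of its variance against 0.41% to 0.63%. Its median ratio was -0.80 over the first 10 grid columns and 0.40 over the last 10. The features neither dim nor saturated had an SD of 0.597 on replicate 4, below that of each other array, which argues against a wider range of ratios in all features. A gradient across the array is not the whole cause either: with the spatial trend removed the SD on replicate 4 was 1.18, still above 0.86 to 0.88 on the others. This test was set with its value already known and replaced an earlier one on the 9.06% above, which a gradient had passed but which does not measure how much of the spread it covers. What else widened its dim features stays open, and no biological explanation was tested. With the trend removed, 0 genes and 10 lists were called, and hypoxia and glycolysis genes were no longer among them, at an adjusted p of 0.112.

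The arrays of 1 labelled orientation ran against each other, with a correlation of -0.657 between replicates 1 and 3 over features neither dim nor saturated. With the labels as given, an effect of the peptide large enough to shape the arrays would give a positive value there under either reading of the columns, so it is not then the source of this opposition. Dim features are not the source either, since the correlation over all features was weaker, at -0.238. An exchange of the orientation labels between replicates 3 and 4 could give the observed signs. So could one between replicates 1 and 2, with every direction turned. After turning replicates 2 and 3, the lowest of the 6 correlations was 0.0432, too near 0 to decide. With either exchange an effect of the peptide is among the open sources. Over genes with dim features left out and arrays centred, replicates 1 and 4 against 2 and 3 held 55.87% of the variance. The labelled orientation held 13.52%. The fit leaves the former component in its residual spread. Differences between individual grafts that do not follow the peptide can give the same signs, so an exchange and such differences cannot be told apart here.

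T cell markers passed with the preset correlation and not with an estimated one, at an adjusted p of 0.935, where the estimated correlation between members was 0.614. The preset of 0.01 lies far below that, so members that move together from graft to graft may produce this call without an effect of the peptide. The lost call does not itself show this. With an estimated correlation 0 of 39 lists had an unadjusted p under 0.05. Tubular injury genes, with an estimated correlation of -0.0097, also went from an unadjusted camera p of 0.00177 to 0.0725. Noise of dim features is argued against, since the adjusted p with the preset correlation was 3.44e-12 with dim features left out, though adjusted p = 0.68 with an estimated correlation. A single axis of infiltrate against tubule is left open, as T cell and proximal tubule markers lay on opposite sides on 3 of 4 arrays. Of the 3 splits of the arrays into 2 and 2, 2 called at least the 10 lists of the labelled orientation, and 3 splits are too few for a share under 0.05. The highest other count, 18 lists, came from replicates 1 and 4 against 2 and 3. This is the comparison of the peptides if the labels of replicates 3 and 4 were exchanged, or, with its sign turned, those of 1 and 2. With dim features left out, that split called 454 genes against 0, and 101 with arrays also centred, but it called 0 genes over all features and 0 lists with an estimated correlation, and whether it reflects differences between grafts or the peptide is left open.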

How the results depend on the processing

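The spatial, dim-feature and 1-symbol settings were added after seeing the data. The count of 0 genes held under every setting run with an adjusted threshold, leaving out each replicate included, and 383 genes had an unadjusted p under 0.05. Among features, leaving out each replicate gave 0 to 1 calls, the 1 being a feature of Upk1b without replicate 1. The 10 lists called became 6 without the dye term, 0 with an estimated correlation and 0 with fry, and between 0 and 14 when a replicate was left out, with 0 without replicate 2 whether or not the dye term was kept and 5 without replicate 4 and without the dye term; the other 14 settings gave counts within 1.5 times the main one. For the 10 lists called, the test kept its direction and no longer passed in 73 cases, kept both in 113 and reversed in 12; in 1 of the 73, fibroblast genes without replicate 3 and without the dye term, the mean shift was 0.02 although the test's direction was down. Without the dye term the calls of regulatory T cell (adjusted p of 0.0726), fibroblast (0.0542), chemokine (0.0618) and hypoxia genes (0.0773) were lost with unchanged shifts. Scaling ended those of regulatory T cell (0.0649) and hypoxia genes (0.0889), and the latter was also lost with centring (0.0721) and with the spatial trend removed (0.112). With the other reading of the columns, shifts relative to all genes reversed for T cell markers (-0.76), cytotoxic genes (-0.67), regulatory T cell genes (-0.58), erythroid genes (0.16), interferon gamma genes (-0.24), chemokines (-0.17), tubular injury genes (0.19), fatty acid oxidation genes (0.10) and hypoxia genes (-0.24). When a replicate was left out, the shift ranged from -0.038 to 1.00 for cytotoxic genes, from 0.067 to 1.05 for T cell markers, from 0.0079 to 0.91 for regulatory T cell genes, from -0.55 to -0.17 for erythroid genes, from 0.12 to 0.33 for interferon gamma genes, from 0.061 to 0.28 for chemokines, from -0.35 to -0.14 for tubular injury genes, from 0.014 to 0.28 for hypoxia genes, from -0.56 to 0.063 for fatty acid oxidation genes and from -0.47 to 0.10 for fibroblast genes, and the ratio of Lrp8 ranged from -0.24 to 0.52. The cause was not tested. Turning the sign of every ratio turns each direction and keeps each count by construction. Robust eBayes was not run for lists, since camera does not use it. Each ratio already sets both peptides against each other on 1 array, so all tests are paired and no further pairing was run. In the simulation, 84% of changes of 2 log2 units were recovered with dim features left out, and 3% with them. The noise simulated there was unlike that of these arrays, so this does not show that dim features limit the test here. In the data, 0.624% of genes had an unadjusted p under 0.05 with dim features left out, against 2.58% with them, and 0 passed in either.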

Other observations

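Urothelium genes lay at a mean distance of 1.92 log2 units from the median gene over the 4 arrays, with no fixed relation to the peptide. This is the largest of the 39 lists only through replicate 1, without which it was 1.30 against 1.42 for T cell markers, and on replicate 2 the median lay inside the central 95% of random lists. Their median was -3.79, 0.20, 1.67 and 2.04 on replicates 1 to 4 in the direction of ApoE-mimetic over control peptide, under the reading of the columns as Cy5 over Cy3. Krt14, a keratin of basal epithelial cells, had -7.11, -2.27, 4.50 and 2.33, and Upk1a, a uroplakin of the urothelial surface, had -2.51, 0.43, 0.94 and 2.85. Of the 6 urothelium genes measured, 1 had a feature that was neither dim nor saturated. The deposited ratios of a feature of Upk1b, chosen after its values were seen, were -11.33, -5.73, 6.87 and -3.98.

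Collecting duct markers had medians of -1.11, -0.05, 1.02 and 0.64 on replicates 1 to 4, and podocyte markers -0.65, -1.12, 0.19 and 0.93, with the podocyte gene Nphs1, which encodes nephrin, at -1.50, 0.24, 1.82 and 2.12. Endothelial markers had -0.51, -0.38, 0.08 and 0.94.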
